A study of Homo sapiens with 12 samples.

How the data were processed

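The values were TPM (transcript abundance scaled to the same total in each library) as deposited by the authors, 1 value per gene and library, for 29607 genes in 12 libraries of 6 groups with 2 replicates each. The labels describe RNeasy extraction, poly(A) selection with oligo-dT, random N6 priming and stranded DNBSEQ sequencing. The processing notes name HISAT, Bowtie2 2.3.4.3, RSEM 1.3.1, DESeq2 1.4.5 and the GRCh38.p13 genome, without the role of each. Read counts were not used here, so no count model was fitted and depth is unknown. The 2 control columns carry no group name; the first was taken as shControl and the second as Vector because their numbers match the library numbers in the labels. That is an inference.

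Genes with at least 1 TPM in at least 2 libraries were tested, 12731 in all. Values were log2(TPM + 1), which makes changes of low genes look smaller. The limma package (3.58.1, R 4.3.3) fitted a mean for each of the 6 groups, with eBayes and a mean-variance trend, and Benjamini-Hochberg adjustment within each comparison; a call is an adjusted p below 0.05. The comparisons were each hairpin and the mean of both against shControl, the inhibitor against shControl, overexpression against Vector, Vector against shControl, sh2 against sh1, the inhibitor against the mean of the hairpins, and the knockdown effect minus the overexpression effect. With 2 libraries per group a permutation test could not reach the threshold, and none was used for calls.

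Lists of genes were fixed before the data were examined, 35 in number, and 34 could be tested. They cover ferroptosis suppressors and drivers, iron handling, NRF2 and glutathione, the ATF4 and ER unfolded protein responses, proteasome, heat shock, lysosome, plasma cell and B cell genes, myeloma oncogenes and drug response genes, MYC targets, ribosomal proteins, cell cycle, p53, BCL2 families, IL6-JAK-STAT3, MAPK, NF-kB and interferon genes, cholesterol, fatty acid, glycolysis and hypoxia, OXPHOS, histones, actomyosin, the death-associated protein kinase family and markers of other cell types. No member of the mitochondrially encoded list was found in the table under the symbols searched. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Each was adjusted over the lists of a comparison. Camera compares a list with the other tested genes, so its call is relative to them and not a change from 0. The median log2 change of all tested genes was 0.03 in the knockdown, 0.08 with the inhibitor and 0.08 with overexpression. Genes named are STK17B and STK17A, a fixed panel of 14, up to 6 higher and 6 lower genes per main comparison with at least 5 TPM and no overlap between libraries, up to 4 members of each list past its test, and genes called in 2 comparisons. Protein-coding genes were added after values were seen, because short RNAs had taken many of the places. Some genes that the rule names are not reported here.

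Alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter at 5 TPM, a fit of only the groups compared, rescaling by the median of ratios, quantile normalization, leaving out the 20 most abundant genes, eBayes without trend, robust eBayes, keeping only calls with an estimated change of 2-fold or more, a replicate block, and leaving out each library. Exchange of the control columns, leaving short RNA, ribosomal RNA and histone genes out of the scale, and quantile normalization for the list tests were added after results were seen. Simulations held known changes of 0.5, 1 and 2 log2 units in genes that were not low. Of the changes of 1 unit the fit recovered 99.0% for the hairpins, 98.5% for the inhibitor and 97.5% for overexpression. False calls, over all sizes together, were 3.95%, 4.55% and 5.45%. In a simulated inhibitor comparison 2.8% of 500 random lists of 25 genes without a shift had an unadjusted camera p below 0.05. Simulated genes and libraries varied independently, so a state shared by a group and correlation between genes are not covered. Gene coordinates come from GENCODE on GRCh38, and 24990 of the symbols matched RefSeq.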

Results

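RNA was sequenced from KMS11, an established human multiple myeloma cell line, in 12 libraries that form 6 groups of 2. Cells carried a control hairpin (shControl), 1 of 2 hairpins against STK17B (sh1 and sh2), an empty vector (Vector) or an STK17B cDNA (overexpression), or received an STK17B inhibitor. STK17B is a serine/threonine kinase of the death-associated protein kinase family. The study's title places it in ferroptosis, an iron-dependent form of cell death driven by lipid peroxidation, and in drug resistance. Values were TPM, a unit that scales each library to the same total, for 29607 genes. The depth of each library is therefore unknown. Between 16577 and 17354 genes were above 0 in a library, and between 11672 and 12353 reached 1 TPM. The labels do not name the inhibitor or give its dose or time. The series design describes control-hairpin cells given inhibitor or vehicle, but no group is labelled as vehicle. Inhibitor libraries were therefore compared with shControl, which is labelled as untreated. Effects of the solvent or of other targets cannot be told apart from those of STK17B. The labels also do not say whether the 2 replicates of a group were grown apart. The p-values therefore measure the spread between these libraries, which can be technical.

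The groups differed in STK17B transcript. STK17B (ENSG00000081320.10; GRCh38, chromosome 2, 196133566 to 196176503, minus strand, a protein-coding gene with 2 annotated transcripts) stood at 27.3 ± 0.24 TPM in shControl (mean ± SD, n = 2), 11.8 ± 1.26 with sh1 and 14.6 ± 0.14 with sh2. On the log2(TPM + 1) scale of the fit, which makes changes look smaller, the mean of the hairpins was 50.1% of shControl (log2 change -0.998, SE 0.073, adjusted p = 7.0e-06, lower in 4 of 4 libraries), with 45.3% for sh1 and 55.3% for sh2. Overexpression raised STK17B from 29.8 ± 2.33 TPM in Vector to 89.3 ± 6.79 TPM, 2.93-fold on the scale of the fit (log2 change 1.55, SE 0.084, adjusted p = 2.4e-06). With the inhibitor STK17B stood at 23.7 ± 1.79 TPM, a log2 difference of -0.20 that did not pass (adjusted p = 0.090) but did after rescaling by the median of ratios (-0.26) and after quantile normalization (-0.29). The transcripts of the cDNA and of the resident gene cannot be separated in these values. STK17A (chromosome 7, 43582758 to 43650713, plus strand), the closest paralog, rose in the knockdown from 34.3 ± 0.57 TPM to 50.8 ± 0.46 with sh1 and 49.4 ± 2.52 with sh2 (log2 change of the mean 0.53, SE 0.040, adjusted p = 8.0e-06). STK17A was also higher with the inhibitor (0.24, adjusted p = 0.0030), a call lost after quantile normalization (0.12), and with overexpression (0.25, adjusted p = 0.0027), a call lost after the median of ratios (0.14) and with the control columns exchanged (0.06), an alternative chosen after seeing the data.

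**Figure D1:**
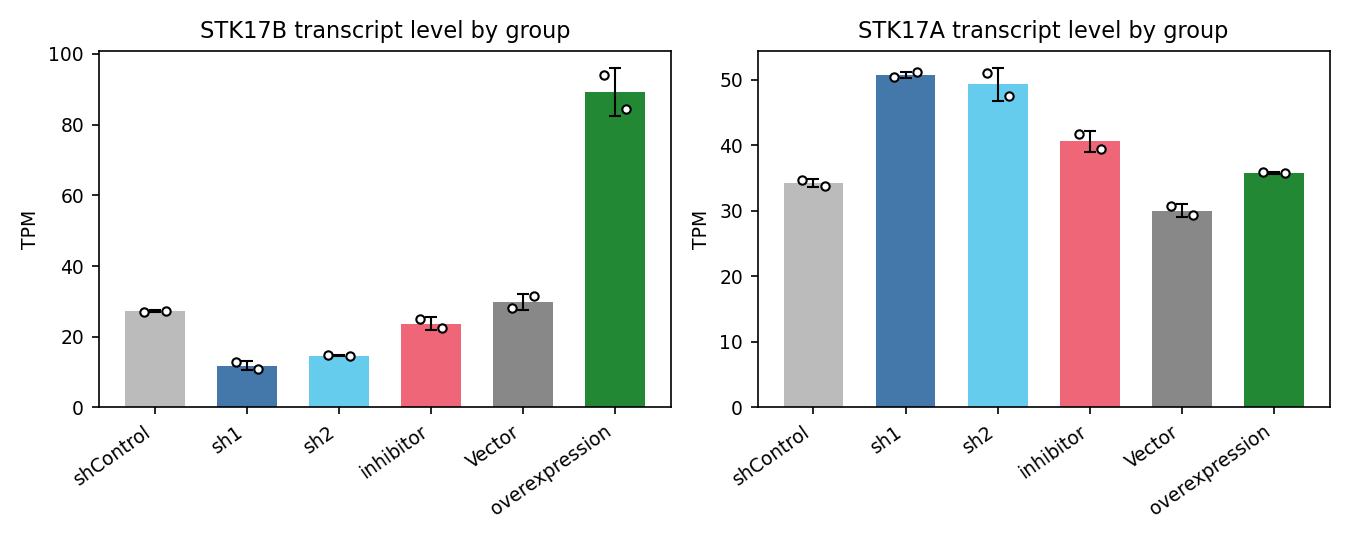
STK17B and STK17A in TPM (vertical axis) in each of the 6 groups; points are single libraries and bars are group means with SD (n = 2). STK17B is at 11.8 and 14.6 TPM with the hairpins, 27.3 TPM in shControl and 89.3 TPM with overexpression, while STK17A is higher with both hairpins than in shControl.

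In the knockdown, which asks what follows from lower STK17B, genes of plasma cell identity fell while B cell and MHC class II genes rose. Of 18 tested plasma cell genes 14 fell and none rose (15 fell adjusted over the list alone), with a median log2 change of -0.42 (camera adjusted p = 3.5e-10). SLAMF7, a surface antigen of plasma cells, fell by 1.24 log2 units (SE 0.073) from 20.3 to 8.11 ± 1.66 TPM (n = 2 and 4). SDC1, which encodes the plasma cell surface marker CD138, fell by 0.98 (SE 0.039), EAF2 fell by 0.87 and TNFRSF17, which encodes BCMA, fell by 0.76 from 298 ± 2.23 to 177 ± 24.5 TPM. Of 14 tested B cell and MHC class II genes 10 rose and none fell (median 0.27, adjusted p = 7.0e-05). Among them were HLA-DMB (0.63), the transcription factor SPIB (0.62), HLA-DPB1 (0.47) and HLA-DRB1 (0.46). Both lists also passed with an estimated correlation. Among 14 myeloma oncogenes 10 fell and 3 rose (11 and 3 adjusted over the list alone; median -0.34, adjusted p = 1.7e-04; adjusted p = 0.15 with an estimated correlation). The transcription factor IRF4 fell by 0.68 from 113 ± 2.79 to 70.4 ± 8.22 TPM, the kinase PIM1 fell by 0.56 and cyclin CCND2 fell by 0.42. Where no second count is given, the count adjusted over the list alone is the same as the count over all genes.

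Growth and cell cycle transcripts were lower in the knockdown than in shControl, but of the lists in this paragraph only the G2/M list also passed against Vector. Of 28 MYC and ribosome biogenesis targets 23 fell and none rose (median -0.21, adjusted p = 9.8e-11), a call that held with an estimated correlation. LDHA, the lactate dehydrogenase A subunit, fell by 0.48, NOLC1 fell by 0.38 and MYC itself fell by 0.36 from 481 ± 15.2 to 375 ± 24.9 TPM. Of 28 G1/S and DNA replication genes 24 fell and none rose (median -0.24, adjusted p = 2.6e-11; adjusted p = 0.085 with an estimated correlation). Cyclin CCNE1 fell by 0.89 from 41.6 ± 0.78 to 22.1 ± 3.28 TPM, the histone mRNA-binding protein SLBP fell by 0.66 and CDC6 fell by 0.50. The G2/M and mitosis list had 15 of 27 members lower and 2 higher (17 and 2 adjusted over the list alone; median -0.11, adjusted p = 0.0017; adjusted p = 0.45 with an estimated correlation). MKI67 was at -0.68 and KIF11 at -0.34. Of 29 genes of glycolysis and hypoxia 22 fell and 2 rose (23 and 2 adjusted over the list alone; median -0.28, adjusted p = 1.8e-09), also with an estimated correlation. In that list ADM, which encodes adrenomedullin, fell by 1.502, ANKRD37 fell by 1.23 from 32.1 ± 0.69 to 13.2 ± 1.90 TPM, and the glucose transporter SLC2A3 rose by 1.08.

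Protein-quality genes were lower in the knockdown than in shControl, and lysosomal and interferon genes were higher. Against Vector the lysosomal, interferon and ATF4 lists did not pass, and the proteasome list passed the other way (0.10). Of 33 genes of the ER unfolded protein response 23 fell and 2 rose (median -0.24, adjusted p = 5.9e-09; adjusted p = 0.14 with an estimated correlation). Among them were TXNDC5 (-0.72), SEC24D (-0.65) and the kinase ERN1 (-0.40). Heat shock chaperones fell in 11 of 18 cases and rose in 2 (median -0.21, adjusted p = 7.4e-05; adjusted p = 0.10 with an estimated correlation). HSPB1 was at -0.52 and HSPA4L at -0.49. The ATF4 amino acid response had 13 of 33 members lower and 3 higher (median -0.09, adjusted p = 0.0044; adjusted p = 0.20 with an estimated correlation): CHAC1 (-0.60), ALDH1L2 (-0.49) and the amino acid transporter SLC7A5 (-0.44) fell, and DDIT3 (0.59) rose. Among 31 proteasome subunits 13 fell and 5 rose (median -0.07, adjusted p = 0.022; adjusted p = 0.21 with an estimated correlation). PSMD2 was at -0.42 and PSMB5 at 0.32; without shControl replicate 1 the list no longer passed (median -0.04), nor did it after quantile normalization (-0.05), which was added for lists after seeing the data. Of 30 genes of autophagy and the lysosome 20 rose and 3 fell (median 0.36, adjusted p = 6.0e-05; adjusted p = 0.085 with an estimated correlation). The cathepsins led: CTSZ (2.003, from 4.37 ± 0.32 to 20.7 ± 3.61 TPM), CTSL (1.05) and CTSA (0.93, from 121 ± 4.25 to 233 ± 20.5 TPM). The type I interferon list had 22 of 30 members higher and 2 lower (23 and 3 adjusted over the list alone; median 0.55, adjusted p = 7.0e-05; adjusted p = 0.20 with an estimated correlation). IFI44 was at 1.60, IRF9 at 1.42, PARP9 at 1.08 and IRF7 at 1.08.

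The largest rise that met the naming rule in the knockdown was RN7SK, the 7SK RNA that holds the elongation factor P-TEFb inactive, from 13.3 ± 1.28 to 99.3 ± 24.9 TPM (log2 change 2.78, SE 0.093, adjusted p = 1.4e-07). RN7SK was also higher with the inhibitor (1.73), with overexpression (2.05) and in Vector against shControl (1.12). Replication-dependent histones, whose mRNAs mostly lack a poly(A) tail, rose in 9 of 14 cases and fell in none (median 0.68, adjusted p = 0.0044; adjusted p = 0.085 with an estimated correlation). HIST1H4H was at 1.996 and HIST1H3H and HIST1H2AC at 1.90. The libraries were made by poly(A) selection, and histone genes share near-identical sequences, so their separate values are uncertain. F2R, which encodes the thrombin receptor PAR1, rose by 2.03 from 2.39 ± 0.15 to 13.1 ± 2.45 TPM. EDNRB, an endothelin receptor, fell by 1.70 from 7.63 ± 0.55 to 1.67 ± 0.25 TPM, GAS6, a ligand of TAM receptor kinases, fell by 1.28, and LGALS17A fell by 1.15. Further protein-coding genes, chosen after their values were seen, were WIPF3 (1.81), CHRNA1 (1.77), CAV1 (-1.10), SULF2 (-1.09) and the interleukin 6 receptor IL6R (-1.09, from 22.7 ± 0.20 to 10.3 ± 1.94 TPM). The T and NK cell marker list held only 2 tested genes, CD7 (0.72) and CD3E (0.59), and passed (adjusted p = 0.040; adjusted p = 0.28 with an estimated correlation).

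Ferroptosis and iron genes did not move as sets in the knockdown. Among 31 ferroptosis suppressors 9 rose and 9 fell (10 and 9 adjusted over the list alone; adjusted p = 0.89). Among 28 drivers 9 rose and 7 fell (9 and 9 adjusted over the list alone; adjusted p = 0.89), and among 27 iron handling genes 6 rose and 9 fell (9 and 11 adjusted over the list alone; adjusted p = 0.73). Of the panel fixed in advance, HMOX1, the heme-degrading oxygenase, rose by 0.93 (22.9 ± 1.03 to 44.8 ± 4.76 TPM), the iron exporter SLC40A1 by 0.80 and the lipid peroxidase GPX4 by 0.26 (302 ± 0.79 to 362 ± 14.2 TPM). ACSL4, which activates polyunsaturated fatty acids, fell by 0.45 and the transferrin receptor TFRC fell by 0.39. Log2 changes of FTH1 (0.05), NCOA4 (0.06), PCBP2 (0.04), IREB2 (-0.12) and STAT3 (-0.07) did not pass; IREB2 passed without sh1 replicate 1 (-0.16) and after both rescalings, STAT3 passed after both rescalings (-0.10) and PCBP2 after quantile normalization (0.10). FTL passed at 0.10 (adjusted p = 0.031), but not without either shControl library, either sh1 library or sh2 replicate 1 (0.08 to 0.13), nor after the median of ratios (0.07). SLC7A11, the cystine transporter, stood between 0.24 and 0.83 TPM in every library and was not tested.

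In all, 3330 of 12731 tested genes were higher and 2570 lower in the mean of the hairpins (limma, Benjamini-Hochberg), 107 and 18 of them by 2-fold or more. Against shControl sh1 gave 3015 higher and 2714 lower, and sh2 gave 2806 higher and 1708 lower. The split for sh2 depended on scaling: 62.2% of its calls were higher, against 47.8% after the median of ratios and 46.8% after quantile normalization. Its counts fell to 1853 higher without sh2 replicate 2, and to 1117 lower without sh2 replicate 1 or 1137 without shControl replicate 2. Both hairpins called 2404 genes higher and 1589 lower, where independent calls would share 664.53 and 364.11, and 3 genes went opposite ways. Across genes, which are not independent replicates, the changes with sh1 and sh2 had a covariance of 0.0994 (r = 0.81), against 0.0147 (r = 0.50) simulated from the shared controls with no effect, where at most 1 call was shared. A division of the controls would leave 1 library per hairpin and was not made, so part of the excess can come from them.

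Between the hairpins themselves, sh2 differed from sh1 in 148 genes higher and 49 lower. Of 34 lists 11 passed, 6 higher and 5 lower with sh2, and 5 of these passed with an estimated correlation. Plasma cell genes stood higher with sh2, the hairpin that left more STK17B transcript, in 9 of 18 cases (11 adjusted over the list alone; median 0.21, adjusted p = 7.8e-10). Histones stood lower in 2 of 14 (5 adjusted over the list alone; median -0.39, adjusted p = 1.9e-05) and autophagy and lysosome genes lower in 2 of 30 (7 adjusted over the list alone; median -0.06, adjusted p = 1.3e-06). MYC and ribosome biogenesis targets stood higher in 3 of 28 (13 adjusted over the list alone; median 0.11, adjusted p = 1.5e-06) and B cell and MHC class II genes lower in 2 of 14 (5 adjusted over the list alone; median -0.07, adjusted p = 5.5e-06). These are the 5 lists. STK17B itself differed by 0.29 between the hairpins and did not pass (adjusted p = 0.12). These counts moved with every library left out, to 70 higher and 12 lower without sh1 replicate 1, 23 and 7 without sh1 replicate 2, 15 and 2 without sh2 replicate 1, and 19 and 3 without sh2 replicate 2. The share of calls that were higher was 75.1%, against 52.6% after the median of ratios and 54.1% after quantile normalization.

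The inhibitor comparison asks what differs in cells given the compound, whose action on the kinase these values do not measure. Hypoxia and glycolysis genes gave its largest group change. Of 29 tested members 28 fell and none rose (median -1.09, adjusted p = 7.6e-38, also past the test with an estimated correlation). PFKFB4, which makes the glycolytic activator fructose 2,6-bisphosphate, fell by 3.18 (SE 0.076) from 19.0 ± 0.19 to 1.21 ± 0.23 TPM (n = 2 and 2), the aldolase ALDOC fell by 2.52 from 151 ± 4.52 to 25.5 ± 0.73 TPM, ADM fell by 2.22 and ANKRD37 fell by 2.06. MIR210HG, the host transcript of the hypoxia-induced microRNA gene MIR210, fell by 2.69. MIR210 itself was listed at 0 in both inhibitor libraries, against 94.1 and 15.6 TPM in the shControl libraries, but it was also at 0 in both Vector libraries, so the call was lost with the control columns exchanged. Cholesterol synthesis genes fell in 15 of 24 cases and rose in 1 (median -0.24, adjusted p = 1.5e-10, also with an estimated correlation). INSIG1 fell from 345 ± 4.66 to 172 ± 4.32 TPM (-0.997), STARD4 changed by -0.93 and FDFT1 by -0.54. Of 20 fatty acid genes 10 fell and 4 rose (10 and 6 adjusted over the list alone; median -0.21, adjusted p = 3.7e-04; adjusted p = 0.28 with an estimated correlation). Among them were the desaturases FADS2 (-2.34, from 102 ± 2.41 to 19.4 ± 0.03 TPM), FADS1 (-1.47) and SCD (-1.27) and the synthase FASN (-0.87).

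Plasma cell genes were lower with the inhibitor too, in 14 of 18 cases (median -0.36, adjusted p = 6.6e-13, also with an estimated correlation). SDC1 fell by 2.13 from 58.5 ± 1.26 to 12.6 ± 0.19 TPM, SLAMF7 fell by 1.19 and EAF2 fell by 0.89. CD38 was the 1 member that rose (0.60, adjusted p = 0.011), from 0.56 ± 0.13 to 1.36 ± 0.16 TPM, and it did not pass without shControl replicate 1 (0.52) or inhibitor replicate 2 (0.53). Of 14 myeloma oncogenes 7 fell and 4 rose (8 and 4 adjusted over the list alone; median -0.13, adjusted p = 0.013; adjusted p = 0.32 with an estimated correlation). PIM1 was at -0.90, MAF at -0.41 and IRF4 at -0.35. Cytosolic ribosomal proteins fell in 28 of 40 cases and rose in none (29 fell adjusted over the list alone; median -0.13, adjusted p = 2.5e-14, also with an estimated correlation). RPL3 changed by -0.33 and RPS3 by -0.32. After quantile normalization the list no longer passed (-0.05). MYC and ribosome biogenesis targets rose in 23 of 28 cases (24 adjusted over the list alone; median 0.26, adjusted p = 4.8e-05; adjusted p = 0.065 with an estimated correlation). RRS1 was at 0.56, RRP12 at 0.48 and NOP2 at 0.47; LDHA was the 1 member that fell over all genes (-0.998, from 1183 ± 0.75 to 592 ± 9.11 TPM), and 2 fell adjusted over the list alone.

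Oxidative stress genes of the NRF2 and glutathione list rose in 15 of 26 cases and fell in 2 with the inhibitor (median 0.14, adjusted p = 0.0054; adjusted p = 0.067 with an estimated correlation). HMOX1 rose by 1.97 from 22.9 ± 1.03 to 92.3 ± 1.78 TPM, OSGIN1 by 0.90, ME1 by 0.78 and the quinone reductase NQO1 by 0.76. In the ATF4 list 14 of 33 members fell and 8 rose (14 and 9 adjusted over the list alone; median -0.08, adjusted p = 0.0044; adjusted p = 0.27 with an estimated correlation). Its largest changes were DDIT4, an inhibitor of mTORC1 that hypoxia also induces (-1.95, from 280 ± 7.57 to 71.8 ± 0.72 TPM), and VLDLR (-1.83), followed by PCK2 (-0.80) and ATF3 (-0.73). ER unfolded protein response genes fell in 12 of 33 cases and rose in 4 (13 and 5 adjusted over the list alone; median -0.06, adjusted p = 9.7e-04; adjusted p = 0.35 with an estimated correlation). HSP90B1 was at -0.44, TXNDC5 at -0.39 and XBP1 at -0.37. Proteasome subunits rose in 15 of 31 cases and fell in none (16 adjusted over the list alone; median 0.10, adjusted p = 0.021; adjusted p = 0.27 with an estimated correlation). Examples were PSMA4 (0.32) and PSMC5 (0.29). G1/S genes rose in 14 of 28 and fell in 1 (15 and 1 adjusted over the list alone; median 0.12, adjusted p = 0.021; adjusted p = 0.46 with an estimated correlation). Examples were MCM5 (0.34) and UHRF1 (0.33). Neither of the last 2 lists passed without shControl replicate 2 (medians 0.08 and 0.11) or after the median of ratios (0.03 and 0.06).

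The ferroptosis lists did not pass with the inhibitor. Suppressors rose in 14 of 31 cases and fell in 3 (median 0.17, adjusted p = 0.063), and passed without shControl replicate 1 (0.15). Drivers had 8 of 28 members higher and 6 lower (adjusted p = 0.95), and iron handling 13 of 27 higher and 3 lower (14 and 3 adjusted over the list alone; adjusted p = 0.17). In the panel the ferritin chains FTH1 (0.63) and FTL (0.35), GPX4 (0.47, from 302 ± 0.79 to 420 ± 12.1 TPM), NCOA4 (0.30) and PCBP2 (0.30) rose, while TFRC (-0.26) and STAT3 (-0.35) fell. With the control columns exchanged FTL (-0.03), NCOA4 (0.16) and TFRC (-0.12) did not pass. ACSL4 passed at -0.39 (adjusted p = 0.012), but not without shControl replicate 1 (-0.38) or inhibitor replicate 2 (-0.31). SLC40A1 (-0.09), IREB2 (-0.01) and MYC (0.04) did not pass.

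Single genes that rose with the inhibitor included ID1, an inhibitor of helix-loop-helix factors, from 20.7 ± 1.23 to 116 ± 0.40 TPM (log2 change 2.43, SE 0.095, adjusted p = 2.4e-07), and CYP1A1, a target of the aryl hydrocarbon receptor, from 1.07 ± 0.43 to 8.13 ± 0.64 TPM (2.15). CYP1A1 was also higher in Vector than in shControl (1.63). Protein-coding genes chosen after their values were seen were GALM (1.34), AMN (1.32), the retinoic acid hydroxylase CYP26A1 (1.18), PPFIA4 (-2.31) and P4HA2 (-2.14). The naming rule also took short RNA genes. SNORA47 was listed at 0 in both shControl libraries and at 5.52 and 5.43 TPM with the inhibitor. SNORD97 was listed at 4.97 and 5.07 TPM in shControl and at 0 with the inhibitor. It was also at 0 in both Vector libraries, so its call was lost with the control columns exchanged. MIR378J (34.97 and 17.7 TPM), SNORA25 (17.7 and 5.86 TPM) and SNORA65 (11.4 and 5.63 TPM) were listed at 0 in shControl, and none of these 3 passed when any 1 of the 4 libraries was left out (log2 change 4.23 to 5.17, 2.78 to 4.23 and 2.73 to 3.63). Poly(A) selection and short lengths make such values uncertain.

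The inhibitor gave 3569 genes higher and 1507 lower than shControl, 47 and 94 of them by 2-fold or more. The share that was higher, 70.3%, depended on scaling and was 55.9% after the median of ratios and 51.9% after quantile normalization. It shared 1491 higher and 687 lower calls with the mean of the hairpins (933.53 and 304.22 for independent calls), while 257 and 585 genes went opposite ways (394.18 and 720.47). The covariance of their changes across genes was 0.0467 (r = 0.41), against 0.01445 (r = 0.57) simulated from the shared controls with no effect, where at most 1 call was shared. Vector, with no STK17B difference past the test, also shared 1370 higher and 527 lower calls with the hairpins (712.24 and 202.07 for independent calls), with a covariance of 0.0411 (r = 0.40) against 0.0147 (r = 0.58) simulated. Such an overlap is thus not particular to the inhibitor, and part of the excess can come from the shared controls. Named as called the same way in both were SNORD97, RN7SK, ADM and GPR75-ASB3, a read-through transcript listed at 0 in both shControl libraries. GPR75-ASB3 stood at 2.97 and 0 TPM with sh1, 3.53 and 5.93 with sh2 and 3.66 and 3.98 with the inhibitor, and its knockdown call was lost without shControl replicate 1 or 2 (1.74). SNORD97 was listed in the knockdown at 4.76 TPM in sh1 replicate 1 and at 0 in the other libraries, and that call too was lost without shControl replicate 1 (-1.97) or 2 (-1.95).

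Tested directly, the inhibitor differed from the mean of the hairpins in 3938 genes higher and 2756 lower. Hypoxia and glycolysis genes were lower with the inhibitor in 29 of 29 cases (median -0.72, adjusted p = 1.5e-19), cholesterol genes in 18 of 24 (1 higher; median -0.45, adjusted p = 8.9e-09) and MHC class II and B cell genes in 9 of 14 (1 higher; 11 and 1 adjusted over the list alone; median -0.24, adjusted p = 2.6e-04). MYC and ribosome biogenesis targets were higher with the inhibitor in 27 of 28 (median 0.46, adjusted p = 2.8e-11). All 4 lists passed with an estimated correlation. Interferon genes were lower in 24 of 30 (1 higher; 25 and 2 adjusted over the list alone; median -0.56, adjusted p = 2.0e-08; adjusted p = 0.070 with an estimated correlation). Plasma cell genes were higher in 7 and lower in 5 of 18 (median 0.02, adjusted p = 0.91), a difference that did not pass.

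Overexpression, which asks what follows from more STK17B, raised 29 of 29 hypoxia and glycolysis genes (median 0.85, adjusted p = 7.3e-25, also with an estimated correlation). CA9, the hypoxia-induced carbonic anhydrase, rose by 3.17 (SE 0.128, adjusted p = 4.3e-07) from 2.29 ± 0.08 to 28.6 ± 0.73 TPM, the enolase ENO2 by 1.87 from 12.6 ± 1.09 to 48.7 ± 1.98 TPM, PFKFB4 by 1.68 and ANKRD37 by 1.44. MIR210 was listed at 0 in both Vector libraries and at 120 and 221 TPM with overexpression. Cholesterol synthesis genes fell in 20 of 24 cases and rose in 1 (median -0.42, adjusted p = 3.1e-17, also with an estimated correlation). The squalene epoxidase SQLE was at -0.75, CYP51A1 at -0.72 and INSIG1 at -0.61. Of 20 fatty acid genes 7 fell and 1 rose (median -0.06, adjusted p = 2.0e-05; adjusted p = 0.18 with an estimated correlation). FADS2 was at -0.90, FASN at -0.82, ACACA at -0.68 and AGPAT2 at 0.83.

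Proteasome, chaperone and translation genes were lower with overexpression, and the lists in this paragraph that give no second p also passed with an estimated correlation. Proteasome subunits fell in 22 of 31 cases (24 adjusted over the list alone; median -0.19, adjusted p = 2.3e-13), such as PSMA5 and PSMB3 (both -0.36). Heat shock chaperones fell in 14 of 18 and rose in 1 (15 and 1 adjusted over the list alone; median -0.24, adjusted p = 7.2e-12): HSPA1B fell from 114 ± 1.20 to 38.5 ± 1.28 TPM (-1.55), HSPA1A by a log2 change of -1.44, DNAJB1 of -0.57 and HSPA8 of -0.51. With the control columns exchanged the list still passed (-0.27), but HSPA1B turned to 0.19 and neither HSPA1A nor DNAJB1 passed. HSPA1A and HSPA1B are near-identical copies whose reads cannot be told apart with certainty. MYC and ribosome biogenesis targets fell in 19 of 28 cases (20 adjusted over the list alone; median -0.21, adjusted p = 3.0e-11). Examples were RRP9 (-0.47) and RRP12 (-0.46), while LDHA was the 1 that rose (0.64). Cytosolic ribosomal proteins fell in 21 of 40 and rose in 1 (25 and 1 adjusted over the list alone; median -0.12, adjusted p = 8.9e-12). Examples were RPL24 (-0.45) and RPS18 (-0.32). Nuclear OXPHOS subunits fell in 15 of 37 and rose in 3 (16 and 3 adjusted over the list alone; median -0.10, adjusted p = 7.0e-06). Examples were NDUFA4 (-0.35) and COX6C (-0.33). ATF4 response genes fell in 20 of 33 and rose in 4 (21 and 4 adjusted over the list alone; median -0.20, adjusted p = 6.4e-09). ALDH1L2 was at -0.98 and CHAC1 at -0.77 but VLDLR at 1.19 and DDIT4 at 0.76. ER unfolded protein response genes fell in 12 of 33 and rose in 3 (13 and 3 adjusted over the list alone; median -0.09, adjusted p = 1.3e-05; adjusted p = 0.21 with an estimated correlation). Examples were HSP90B1 (-0.48) and SEC61B (-0.44). G1/S genes fell in 6 of 28 and rose in 5 (8 and 5 adjusted over the list alone; median -0.05, adjusted p = 0.0093; adjusted p = 0.43 with an estimated correlation). Examples were PCNA (-0.28) and GINS2 (-0.27).

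Plasma cell genes fell in 11 of 18 cases and rose in 3 with overexpression (median -0.24, adjusted p = 1.2e-07, also with an estimated correlation). SDC1 fell by 1.06 from 51.4 ± 0.18 to 24.0 ± 1.01 TPM, SLAMF7 fell by 1.03, EAF2 fell by 0.57 and POU2AF1 fell by 0.44. B cell and MHC class II genes fell in 8 of 14 (8 fell and 1 rose adjusted over the list alone; median -0.13, adjusted p = 8.1e-06, also with an estimated correlation). Among them were HLA-DMA (-0.49) and the class II transactivator CIITA (-0.44). Interferon genes fell in 4 of 30 and rose in 2 (median -0.08, adjusted p = 0.049; adjusted p = 0.50 with an estimated correlation). OASL was at -0.92 and SAMD9L at -0.62, and the list did not pass without Vector replicate 2 (0.09) or overexpression replicate 1 (0.00), nor after the median of ratios (-0.16). A pseudocount of 0.1 (-0.09) or a replicate block (-0.08) also ended the call. Of 23 actomyosin genes 12 rose and none fell (median 0.16, adjusted p = 0.0020; adjusted p = 0.21 with an estimated correlation). Examples were TAGLN2 (0.47) and ACTG1 (0.34). The list's call was lost after the median of ratios (0.06). The T cell markers CD7 (0.92, from 225 ± 9.38 to 426 ± 22.4 TPM) and CD3E (0.77) rose, the 2 tested members of their list (adjusted p = 0.019; adjusted p = 0.22 with an estimated correlation).

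Of 31 ferroptosis suppressors 7 fell and 3 rose with overexpression (median -0.04, adjusted p = 0.0097; adjusted p = 0.068 with an estimated correlation). SCD was at -0.66, SLC3A2 at -0.51, NQO1 at -0.41 and FTL at 0.42. NRF2 and glutathione genes fell in 10 of 26 cases and rose in 6 (median -0.10, adjusted p = 0.0014, also with an estimated correlation), with EPHX1 and ME1 at -0.44, while HMOX1 rose by 1.16 from 27.7 ± 0.76 to 63.2 ± 2.32 TPM. With the control columns exchanged the suppressor list no longer passed (0.07). The NRF2 list still passed as lower relative to the other genes, with a median of 0.06 where that of all genes was 0.18. EPHX1 turned to 0.24. Drivers had 4 of 28 members higher and 5 lower (adjusted p = 0.43) and iron handling 6 of 27 higher and 6 lower (adjusted p = 0.64). In the panel GPX4 passed at 0.15 (adjusted p = 0.013), but not without Vector replicate 2 (0.09) or overexpression replicate 1 (0.13), nor after the median of ratios (0.04). NCOA4 passed at 0.24 (adjusted p = 0.014), but not without Vector replicate 1 (0.18) or overexpression replicate 1 (0.20), nor after the median of ratios (0.13). IRF4 fell by 0.35. Log2 changes of TFRC (-0.13), FTH1 (-0.07), SLC40A1 (-0.20), ACSL4 (-0.05), PCBP2 (0.01), IREB2 (0.12), STAT3 (0.00) and MYC (0.06) did not pass, though TFRC (-0.24), FTH1 (-0.18), PCBP2 (-0.10) and STAT3 (-0.10) did after the median of ratios.

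**Figure D2:**
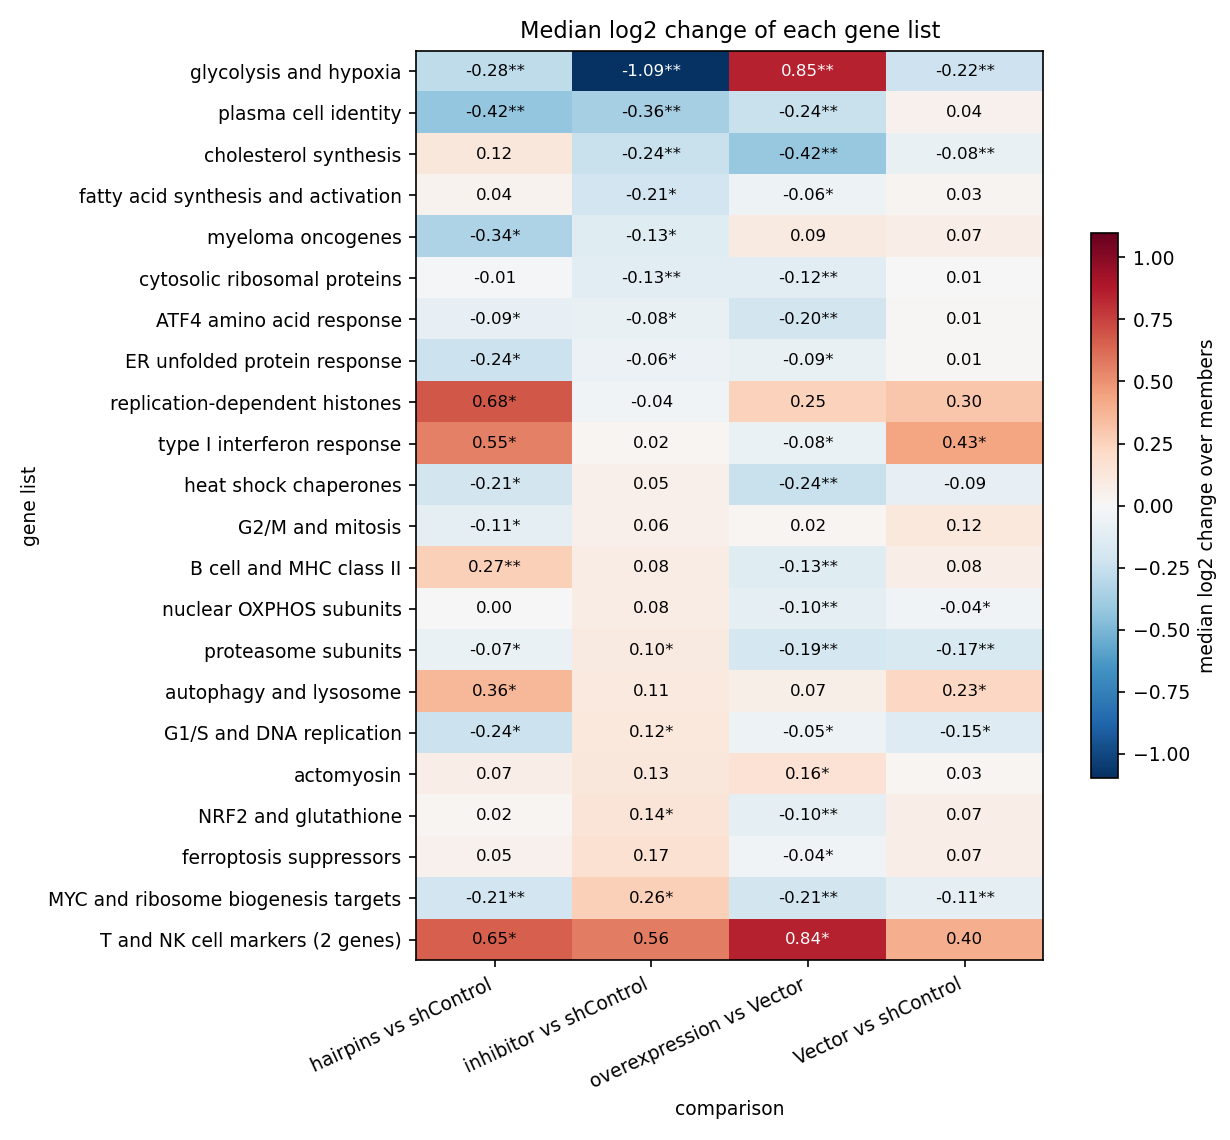
Median log2 change of the tested members of each gene list past the test at least once (vertical axis) in each of 4 comparisons (horizontal axis), on a colour scale in log2 units; 1 star marks a list past the camera test, and a pair of stars also with an estimated correlation. The glycolysis and hypoxia list is at -0.28 in the knockdown, -1.09 with the inhibitor and 0.85 with overexpression, and the plasma cell list is below 0 in all of these.

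Other genes that rose with overexpression, chosen after their values were seen, were the lactate exporter SLC16A3 (1.89), PPFIA4 (1.84), IGFBP4 (1.74) and TXNIP (1.70, from 80.0 ± 1.23 to 261 ± 5.63 TPM); HSPA6 (-1.44), NLRP7 (-1.09) and LILRB4 (-1.07) fell. The naming rule took short RNAs here too. RNA5S1 was listed at 0 in Vector and at 18.4 and 45.6 TPM with overexpression, and SNORA71D at 10.97 and 11.4 TPM in Vector and at 0 with overexpression. SNORA41 (6.71 and 33.4 TPM) and SNORA31 (7.02 and 13.98 TPM) were listed at 0 in Vector, SNORD12B (48.0 and 47.7 TPM in Vector) and SNORA20 (6.19 and 19.0 TPM in Vector) at 0 with overexpression, and SNORA72 stood at 0 and 6.34 TPM in Vector and at 26.8 and 26.7 TPM with overexpression. SNORA63 stood at 34.8 and 23.9 TPM in Vector and 6.27 in both overexpression libraries (-2.04). Each of these last 6 lost its call when some single library was left out. Each also lost it with the control columns exchanged, where SNORD12B was at 0 in both shControl libraries. SNORA31, SNORD12B and SNORA20 lost it without any 1 of the 4 (log2 change 3.003 to 3.91, -5.61 and -4.32 to -2.85), SNORA41 without either Vector library (4.03) or overexpression replicate 2 (2.95), SNORA72 without Vector replicate 1 (1.92) or either overexpression library (3.35 and 3.36), and SNORA63 without Vector replicate 1 (-1.78). The counts were 3381 genes higher and 1308 lower, 102 and 20 of them by 2-fold or more. The share that was higher, 72.1%, was 43.2% after the median of ratios (1987 higher, 2614 lower) and 46.3% after quantile normalization (2210 higher, 2566 lower), which moves the median of all genes by -0.10.

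The 2 control groups give the background. Which control column belongs to which group is an inference from the library numbers in the labels. Mean correlations were higher with the assigned control than with the other, by little for the hairpins. They were 0.982 against 0.980 for sh1 and 0.985 against 0.984 for sh2. For the inhibitor they were 0.985 against 0.978, and for overexpression 0.983 against 0.978. These values do not settle the assignment. Each comparison of a changed group with its control was therefore repeated with the control columns exchanged, an alternative chosen after seeing the data. The overlaps and covariances between comparisons were not repeated in this way. Vector and shControl differed in 2723 genes higher and 1001 lower in Vector, 83 and 6 by 2-fold or more, without a STK17B difference past the test (0.12, adjusted p = 0.30), while STK17A was lower in Vector (-0.19, adjusted p = 0.015). Of the calls 73.1% were higher, against 43.0% after the median of ratios and 48.4% after quantile normalization, which moves the median of all genes by -0.11. Counts fell to 1516 higher and 587 lower without shControl replicate 1, to 1468 and 627 without Vector replicate 2, and to 619 lower without shControl replicate 2. Proteasome subunits fell in 21 of 31 cases (median -0.17, adjusted p = 4.1e-17) and hypoxia genes in 19 of 29 (19 fell and 1 rose adjusted over the list alone; median -0.22, adjusted p = 4.7e-15). MYC and ribosome biogenesis targets fell in 11 of 28 (12 adjusted over the list alone; median -0.11, adjusted p = 3.6e-10) and cholesterol genes in 7 of 24 (8 adjusted over the list alone; median -0.08, adjusted p = 1.3e-05), all 4 also with an estimated correlation. Past the test but not with an estimated correlation were G1/S genes (17 of 28 lower, median -0.15, adjusted p = 4.4e-13; adjusted p = 0.068 with an estimated correlation) and lysosome genes (17 of 30 higher, 19 adjusted over the list alone, median 0.23, adjusted p = 2.3e-05; adjusted p = 0.065 with an estimated correlation). So were interferon genes (16 of 30 higher, 19 adjusted over the list alone, median 0.43, adjusted p = 1.6e-04; adjusted p = 0.35 with an estimated correlation). Nuclear OXPHOS subunits (11 of 37 lower and 6 higher; 12 and 8 adjusted over the list alone) passed too (median -0.04, adjusted p = 2.2e-04; adjusted p = 0.065 with an estimated correlation), but not after quantile normalization (-0.02). Ribosomal proteins passed only after the median of ratios (-0.10), and G2/M genes after quantile normalization (0.10) or with fry (0.12).

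With the control columns exchanged, 3574 of 5900 knockdown calls were kept and 309 reversed, 3835 of 5076 inhibitor calls were kept and 127 reversed, and 4020 of 4689 overexpression calls were kept and 64 reversed. Among the lists, the knockdown kept its calls for plasma cell genes (median -0.51), ER unfolded protein response genes (-0.25), heat shock chaperones (-0.18), B cell and MHC class II genes (0.17), myeloma oncogenes (-0.39), G2/M genes (-0.16) and histones (0.64). It lost those for hypoxia genes (-0.03), MYC and ribosome biogenesis targets (-0.07), G1/S genes (-0.12), lysosome genes (-0.03), interferon genes (0.18), the ATF4 response (-0.15) and the T cell markers (0.25). Proteasome subunits turned and lay higher in the knockdown (median 0.10 against -0.07). Cholesterol genes (0.23) and OXPHOS subunits (0.09), not past the test against shControl, passed. The inhibitor kept its calls for hypoxia (-0.99), plasma cell (-0.57), cholesterol (-0.14), ribosomal protein (-0.14), fatty acid (-0.31), MYC target (0.37), proteasome (0.28), G1/S (0.27) and NRF2 genes (0.18) and myeloma oncogenes (-0.18), and lost those for the ATF4 response (-0.05) and the ER unfolded protein response (-0.13). Its interferon (-0.39) and OXPHOS lists (0.12) passed, and lysosome genes passed with a median of -0.21 in place of 0.11. Overexpression kept hypoxia (0.70), cholesterol (-0.49), proteasome (-0.33), heat shock (-0.27), plasma cell (-0.08), MYC target (-0.35), ATF4 response (-0.20), G1/S (-0.18), ribosomal protein (-0.13), OXPHOS (-0.11), fatty acid (-0.10), ER unfolded protein response (-0.06), and B cell and MHC class II genes (-0.06). The NRF2 list still passed as lower relative to the other genes. Its median went from -0.10 to 0.06, where the median of all genes was 0.18. Overexpression lost interferon (0.39), actomyosin (0.27), ferroptosis suppressors (0.07) and the T cell markers (1.245), while lysosome genes passed (0.37). Among single genes, CD7 in the knockdown (0.03), STK17A (0.06), HSPA1A (-0.05) and DNAJB1 (-0.04) with overexpression, and TFRC (-0.12) and NCOA4 (0.16) with the inhibitor no longer passed, and HSPA1B (0.19) and HSPA6 (0.83) were higher with overexpression. FTL turned from 0.10 to -0.28 in the knockdown, while EPHX1 went from -0.44 to 0.24 with overexpression. DDIT3 went from 0.59 to -0.28 in the knockdown, which did not pass. Panel genes that passed on exchange but not before were FTH1 (-0.22), IREB2 (-0.21) and STAT3 (-0.11) in the knockdown, and TFRC (-0.27), FTH1 (0.20), IREB2 (0.21) and MYC (0.14) with overexpression. STK17B passed too with the inhibitor (-0.32).

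Knockdown and overexpression, which share no library, were set against each other in a test of the difference of their effects. Hypoxia and glycolysis genes lay lower in the knockdown effect in 28 of 29 cases and higher in 1 (median difference -1.13, adjusted p = 7.3e-28), and B cell and MHC class II genes lay higher in 10 of 14 and lower in 1 (0.51, adjusted p = 1.4e-09). Cholesterol genes lay higher in 20 of 24 and lower in 1 (20 and 2 adjusted over the list alone; 0.56, adjusted p = 7.1e-13), and all 3 lists passed with an estimated correlation. Plasma cell genes lay lower in 9 of 18 and higher in 1 (-0.26, adjusted p = 0.014; adjusted p = 0.26 with an estimated correlation). Named as called in opposite directions were ANKRD37 (-1.23 and 1.44), LDHA (-0.48 and 0.64), PLOD1, a collagen lysyl hydroxylase (-0.87 and 1.27), and the glycolytic kinase PGK1 (-0.39 and 0.85). In all, 1445 genes lay higher and 2361 lower; 38.0% were higher, against 55.6% after the median of ratios and 52.0% after quantile normalization. Opposite calls were fewer than independence gives: 183 genes were higher in the knockdown and lower with overexpression (342.13 for independent calls) and 479 the reverse (682.52), while 1490 were higher in both (884.36) and 649 lower in both (264.05). Inhibitor and overexpression shared 1061 higher and 275 lower calls (947.83 and 154.83) and opposed each other in 494 and 536 (366.68 and 400.22). These overlaps were not repeated with the control columns exchanged, so how far they depend on the controls is not known.

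**Figure D3:**
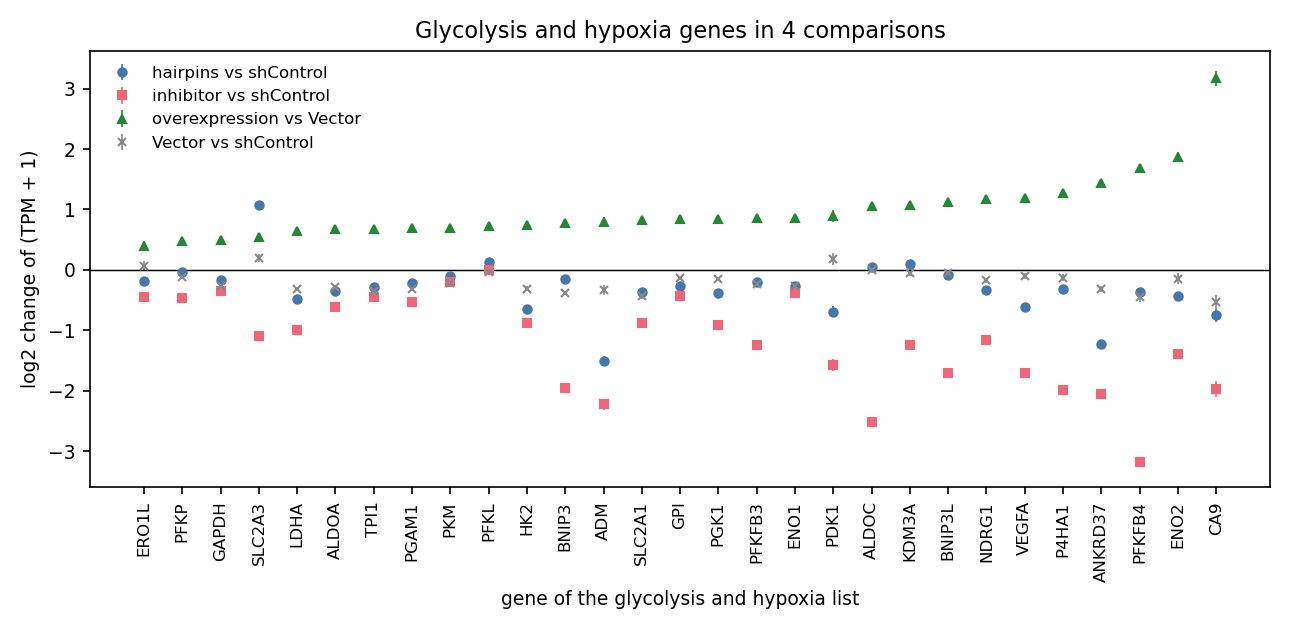
Log2 change with SE (vertical axis) of each tested glycolysis and hypoxia gene (horizontal axis) in the knockdown, with the inhibitor, with overexpression and in Vector against shControl. With the inhibitor 28 of 29 genes passed below 0, and with overexpression 29 of 29 passed above 0.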

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

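For the hypoxia pattern, each test below was chosen only after the result was seen. Glycolysis and hypoxia genes were lower with the inhibitor (median -1.09) and higher with overexpression (0.85), and the difference between the knockdown and overexpression effects was -1.13 (medians -0.28 and 0.85; adjusted p = 7.3e-28, 28 of 29 lower and 1 higher; adjusted p = 0.0043 with an estimated correlation). Rescaling argues against a scaling effect, since the smallest median over both comparisons was still 0.73 in size, and exchange of the control columns left at least 0.70. The fall in the knockdown alone is another matter, because against Vector its median was -0.029. This restates the difference between the controls, where the list's mean log2 value was 7.05 in shControl and 6.85 in Vector. Vector was the control for overexpression and not for the hairpins, so which control stands apart cannot be told. A culture state shared by a group, such as density or oxygen, stays open: replicates differed by at most 0.037 in the list's mean log2 value, which ran from 5.86 with the inhibitor to 7.84 with overexpression, and the labels do not say whether replicates were grown apart.

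For the plasma cell pattern, each test was also chosen only after the result was seen. Plasma cell genes were lower in the knockdown (-0.42), with the inhibitor (-0.36) and with overexpression (-0.24). Scaling is argued against by 6 of 6 rescaled tests that stayed past the threshold below 0. The list fell with less STK17B transcript and, at -0.24, with more, which is not a steady rise or fall with it. This restates the pattern and is no separate test of it. With the control columns exchanged the overexpression median was -0.079 (8 of 18 lower and 4 higher, still past the test). A difference between controls is argued against for the knockdown and the inhibitor, where the exchange left medians of -0.51 and -0.57, but stays open as a part of the overexpression fall, given that -0.079. The marker lists cannot decide on RNA from other cell types, because they hold 2 tested genes each and the test value was 0.0064. All libraries are labelled as the cell line KMS11, so the labels give no source of other cell types.

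For RN7SK and histones, the short RNA test was written in advance and the others were chosen only after the result was seen. RN7SK rose by 2.78 and the histone list had a median of 0.68 in the knockdown. A shift towards S phase, which would raise G1/S genes, is argued against by their median of -0.24, though the list did not pass with an estimated correlation (adjusted p = 0.085) or against Vector (-0.12, 15 of 28 lower and 3 higher). A difference between controls as the whole cause is argued against by a histone median of 0.64 and an RN7SK change of 1.67 against Vector, though RN7SK was itself 1.12 higher in Vector than in shControl and with sh2 alone the histone list no longer passed (0.375). More RNA without a poly(A) tail stays open. The 99 small nucleolar RNA genes had a median of -0.10, and the rule written in advance counted a median at or below 0 against it. That rule did not allow for the spread of these genes, whose quartiles were -0.76 and 0.68. The 7SK, 7SL, U and Y class of 20 genes had a median of 0.71, with 3 called higher and 0 lower. This class was not part of the rule and includes RN7SK itself. RNR2, a ribosomal RNA symbol, stood at 0.234% and 0.280% of TPM in shControl and at 0.463% and 0.544% in Vector. With the hairpins it stood between 0.523% and 0.645%. Whether the RNR2 transcript has a poly(A) tail was not established, so its rise decides nothing here.

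B cell and MHC class II genes lay 0.51 higher in the knockdown than in the overexpression effect (medians 0.27 and -0.13; adjusted p = 1.4e-09; adjusted p = 0.0056 with an estimated correlation; 10 of 14 higher, 1 lower). Interferon genes differed by 0.64 in the same contrast (0.55 and -0.08; adjusted p = 1.2e-09; adjusted p = 0.089 with an estimated correlation; 20 of 30 higher, 1 lower). With the control columns exchanged, an alternative chosen after seeing the data, the interferon medians were 0.18 in the knockdown and 0.39 with overexpression. Neither passed the test, so the order of these medians depends on the controls. Proteasome subunits were 0.17 higher with the inhibitor than with the hairpins (medians -0.07 in the knockdown and 0.10 with the inhibitor; adjusted p = 6.8e-05; adjusted p = 0.058 with an estimated correlation; 23 of 31 higher, 1 lower). MYC and ribosome biogenesis targets were 0.46 higher with the inhibitor than with the hairpins (-0.21 and 0.26; adjusted p = 2.8e-11; adjusted p = 0.013 with an estimated correlation; 27 of 28 higher, 1 lower). G1/S genes were 0.41 higher with the inhibitor than with the hairpins (-0.24 and 0.12; adjusted p = 8.8e-12; adjusted p = 0.058 with an estimated correlation; 28 of 28 higher).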

How the results depend on the processing

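Of 2972 gene tests under the alternatives chosen in advance 2927 gave the same call, and of 612 list tests with other scaling, pseudocount or block 602 did. The gene tests, here and with a library left out, cover only named genes, many of them named because they were called. Over all calls fewer were kept after rescaling. The median of ratios kept 5525 of 5900 knockdown, 4026 of 5076 inhibitor, 3294 of 4689 overexpression and 2660 of 3724 Vector calls. Quantile normalization kept 5315, 3470, 3468 and 2398 of them. An estimated correlation gave the same list call in only 149 of 204 tests and fry in 142 of 204. With a library left out 1196 of 1256 gene tests and 870 of 884 list tests did, assuming that the lone library left in a group varies like the other groups. Of the calls, those with an estimated change of 2-fold or more were 126 higher and 45 lower for sh1, 86 and 13 for sh2, 107 and 18 for their mean, 47 and 94 for the inhibitor, 102 and 20 for overexpression, 83 and 6 for Vector, 6 and 1 for sh2 against sh1, 36 and 117 for the inhibitor against the hairpins, and 87 and 132 for the knockdown minus the overexpression effect. Quantile normalization gave 2105 higher for the inhibitor, 2210 higher and 2566 lower for overexpression, 1549 and 1651 for Vector, and 90 lower for sh2 against sh1. The median of ratios gave 1987 higher and 2614 lower for overexpression, 1659 and 2200 for Vector, and 51 higher for sh2 against sh1. For sh2 against sh1, no filter gave 79 higher, a filter at 5 TPM 251 higher and 80 lower, leaving out the most abundant genes 93 higher, the replicate block 87 and 27, only the groups compared 4 and 1, and eBayes without trend 15 and 6. With 1 library left out, sh2 gave 1853 (without sh2 replicate 2) to 2123 higher and 1117 (without sh2 replicate 1) to 1173 lower, with 1137 lower without shControl replicate 2. Vector gave 1468 (without Vector replicate 2) to 2093 higher and 587 (without shControl replicate 1) to 739 lower. For sh2 against sh1 the range was 15 (without sh2 replicate 1) to 70 (without sh1 replicate 1) higher, and 2 to 12 lower without the same libraries. Lists past the test with an estimated correlation numbered 2 for sh1, 4 for sh2, 4 for their mean, 4 for the inhibitor, 11 for overexpression and 4 for Vector, and with fry 24 for sh1, 25 for the mean, 24 for the inhibitor and 23 for Vector. Differences between replicates showed little correlation between groups (median -0.006 over 15 pairs, from -0.10 to 0.14). That cannot exclude that libraries with the same replicate number were handled together, which the labels do not say.

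With the control columns exchanged, an alternative chosen after seeing the data, sh2 gave 2814 lower genes and 10 lists past the test, the inhibitor 3434 lower, overexpression 5721 higher and the knockdown minus the overexpression effect 5763 lower, where the median of all genes moved by -0.19. In the knockdown these turned: DDIT3 (-0.28 from 0.59), PSMB6 (0.034 from -0.28), RRP9 (0.034 from -0.38), FTL (-0.28 from 0.10), SNORD97 (0.63 from -1.96) and GPR75-ASB3 (-1.05 from 1.74). With the inhibitor FTL (-0.032 from 0.35) and GPR75-ASB3 (-0.52 from 2.27) turned. With overexpression HSPA1B (0.19 from -1.55), HSPA6 (0.83 from -1.44), EPHX1 (0.24 from -0.44) and CD79B (0.054 from -0.29) did. Of these genes only FTL in the knockdown and HSPA1B, HSPA6 and EPHX1 with overexpression passed in the new direction. The others changed sign without a call. The proteasome list turned and passed for sh1 (0.11), sh2 (0.11) and their mean (0.10). The interferon list turned for overexpression (0.39) but did not pass. The cause was not tested.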

Other observations

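Several lists did not pass in any of the knockdown, inhibitor and overexpression comparisons. In the knockdown p53 targets had 6 of 19 members higher and 6 lower (median 0.01, adjusted p = 0.89, given in this order below), myeloma drug response genes 5 of 19 higher and 5 lower (5 and 6 adjusted over the list alone; -0.02, 0.61), antiapoptotic BCL2 genes 1 of 4 higher and 1 lower (-0.04, 0.69), proapoptotic BCL2 genes 4 of 9 higher and 1 lower (0.15, 0.17), IL6-JAK-STAT3 genes 5 of 16 higher and 4 lower (-0.09, 0.69), MAPK output 1 of 12 higher and 4 lower (-0.12, 0.24), NF-kB targets 8 of 17 higher and 2 lower (8 and 3 adjusted over the list alone; 0.13, 0.15) and the death-associated protein kinase family 1 of 4 higher and 1 lower (0.01, 0.91). Myeloid markers (0.01, 0.96) and stromal and epithelial markers (-0.20, 0.44) held 2 tested genes each. Also not past the test in the knockdown were NRF2 and glutathione (0.02, 0.93), ribosomal proteins (-0.01, 0.74), cholesterol synthesis (12 of 24 higher and 4 lower, 14 and 4 adjusted over the list alone; 0.12, 0.050), which passed after quantile normalization (0.15; added for lists after seeing the data), fatty acid genes (0.04, 0.69), OXPHOS subunits (-0.00, 0.74) and actomyosin (0.07, 0.17), which passed after quantile normalization (0.11). With the inhibitor the lists not past the test were p53 targets (0.07, 0.73), drug response (0.11, 0.99), antiapoptotic (-0.15, 0.13) and proapoptotic BCL2 genes (0.21, 0.19), IL6-JAK-STAT3 (-0.07, 0.063), MAPK output (-0.16, 0.066), NF-kB targets (0.03, 0.62), interferon (0.02, 0.066), OXPHOS (0.08, 0.063), G2/M (0.06, 0.97), heat shock (0.05, 0.99), lysosome (0.11, 0.40), B cell and MHC class II (0.08, 0.57), histones (-0.04, 0.47), actomyosin (0.13, 0.31), the kinase family (0.01, 0.88) and the T cell (0.56, 0.074), myeloid (0.08, 0.89) and stromal markers (-0.12, 0.58). Without shControl replicate 1 IL6-JAK-STAT3 (-0.00) and OXPHOS (0.11) passed, and without inhibitor replicate 1 the T cell markers did (0.64). With overexpression they were p53 targets (0.15, 0.81), drug response (0.08, 0.94), antiapoptotic (0.19, 0.79) and proapoptotic BCL2 genes (0.03, 0.87), IL6-JAK-STAT3 (0.02, 0.20), MAPK output (0.08, 0.79), NF-kB targets (0.04, 0.79), G2/M (0.02, 0.43), which passed after the median of ratios (-0.09), lysosome (0.07, 0.19), myeloma oncogenes (0.09, 0.87), histones (0.25, 0.79), the kinase family (0.19, 0.20) and the myeloid (0.07, 0.87) and stromal markers (0.01, 0.81). In the lists that passed, the median, the mean and the test had the same sign, while 7, 9 and 10 lists not past the test in these comparisons had signs that differed.

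HMOX1, whose product degrades heme and releases iron, was higher in the knockdown, with the inhibitor and with overexpression. HMOX1 stood at 22.9 ± 1.03 TPM in shControl, 47.7 ± 5.63 with sh1, 41.8 ± 1.33 with sh2, 92.3 ± 1.78 with the inhibitor, 27.7 ± 0.76 in Vector and 63.2 ± 2.32 with overexpression (n = 2 each), and in Vector it was 0.26 above shControl (adjusted p = 0.021). CYP1A1 rose as well in the knockdown (0.59, adjusted p = 0.0033), with the inhibitor (2.15) and with overexpression (0.62, adjusted p = 0.0068). In Vector CYP1A1 was 1.63 above shControl, and with the control columns exchanged, an alternative chosen after seeing the data, its knockdown change turned to -1.05, with 0.52 for the inhibitor and 2.26 for overexpression. MIR210HG, the host transcript of MIR210, stood at 11.6 TPM in shControl, 0.96 with the inhibitor and 41.7 with overexpression.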
